A study of Homo sapiens with 8 samples.

How the data were processed

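RNA was measured in 8 libraries of HepG2 cells, an established line of human hepatocellular carcinoma: 4 libraries of cells infected with a control lentivirus and 4 of cells infected with a lentivirus that overexpresses DNMT3A, a de novo DNA methyltransferase. Per the labels' protocols, messenger RNA was captured from total RNA on poly-T beads, primed with random hexamers and made into libraries with a preferred fragment length of 370 to 420 bp; the protocol names no step that marks strand. The authors aligned reads with HISAT2 2.0.5 to hg38, per the submitters' processing notes; the counting program and its settings are not given in the sources used here. The deposited values are FPKM (fragments scaled by gene length and library total), 1 column per library, per the file headers. FPKM divides by gene length and by a library total, so a large change in a few abundant genes shifts the values of all others.

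The table held 58735 genes, and the coordinates of 58735 were identical to those of GENCODE release 29. Multiplying FPKM by gene length gave whole multiples of 1 step per library for 100% of values (tolerance 0.01 of a read), from which whole reads were recovered. They summed to 15938744, 17114943, 15911019 and 17677093 reads in control libraries 1 to 4 and to 17560229, 17626137, 17301298 and 17232809 reads in DNMT3A libraries 1 to 4. The library total that the step implies was 0.9942 to 1.0388 times these sums, for a reason not given in the sources used here. No pair of libraries was a duplicate: the chi-square per degree of freedom was 4.87 to 26.76 within groups and 22.11 to 38.65 between groups.

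Groups and replicate numbers were taken from the sample titles. Genes with a mean FPKM of at least 1 over the 8 libraries were tested, which left 11620. Values were transformed to log2(FPKM + 1), where a fold change understates that of low genes, and compared with limma 3.58.1 in R 4.3.3 (moderated variance with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists written before the data were examined (48 lists, of which 43 had at least 5 tested members) were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Members were matched by the symbol in the table, and 55 that had no such symbol were left out. Single values were compared with a two-sided exact permutation test over 70 assignments. On simulated data with 200 changed genes per run among the 11620 genes of this comparison, limma recovered 15.6% of log2 changes of 0.3, 65.6% of 0.5, 95.6% of 1 and 100% of 2, and 4.79% of calls were false. The simulated spread was independent between genes, so those shares do not cover correlated genes. Changed genes were not drawn from the lowest tested levels, so the recovered shares do not cover low genes. Fewer genes were changed per run than were called in the data, so the shares there may differ.

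A rule fixed in advance set which genes could be named. It took DNMT3A, and the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap. From each list it allowed up to 4 members past the threshold with the largest change and up to 2 others with the highest mean. Which of the allowed list members are named was chosen while writing, after values were seen. Genes outside this rule are named as such. Alternatives fixed in advance were another pseudocount, no filter, median-ratio scaling, quantile normalization, no trend, array weights, the replicate number as a block, the other list tests and leaving out each library. Alternatives chosen after the data were seen were voom on the recovered reads, protein-coding genes only, list members matched by gene ID, a spline correction of each library on gene length and GC content, and leaving out chromosomes 13 and 14. A test for raw counts had been planned in case the table held counts and was not used, since it holds FPKM. The labels do not say that the libraries of a group came from separate infections or cultures, so p-values measure only the spread between these libraries, which may be technical.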

Results

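Poly(A) RNA was profiled in HepG2 cells to describe how the transcriptome differs when DNMT3A is overexpressed. There were 4 control libraries and 4 DNMT3A libraries, with 15911019 to 17677093 recovered reads each. Values are mean FPKM ± SD with n = 4 per group, fold changes are DNMT3A minus control on the log2(FPKM + 1) scale, and adjusted p is limma's with Benjamini-Hochberg adjustment unless another test is named.

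DNMT3A itself was higher in every DNMT3A library than in any control library. Its level (ENSG00000119772, hg38 chromosome 2, 25227855 to 25342590, minus strand) was 3.65 ± 0.178 FPKM in the controls and 8.93 ± 1.33 FPKM in the DNMT3A libraries. The log2 fold change was 1.09 (limma adjusted p = 0.000122, two-sided exact permutation p = 0.0286, the smallest that 70 assignments can give). The FPKM covers the whole annotated gene, so transgene and endogenous transcripts were not told apart. Among other genes of DNA methylation, TET1, which oxidises methylcytosine, rose by a log2 of 0.41 (limma adjusted p = 0.00856) and UHRF2 by 0.30 (limma adjusted p = 0.0321). The maintenance methyltransferase DNMT1 (log2 0.03), DNMT3B (log2 -0.15) and UHRF1 (log2 -0.01) did not pass the test. Of the 20 tested members of this list 2 rose and 0 fell, 1 and 0 when adjusted over the list alone. UHRF2 lost its call without a filter (limma adjusted p = 0.0922) and without control library 1, 2 or 3 or DNMT3A library 3 or 4 (0.0581 to 0.0823). DNMT3B passed the threshold without DNMT3A library 2 (0.0394), with array weights (0.0161) and with the length and GC correction (0.0444).

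**Figure D1:**
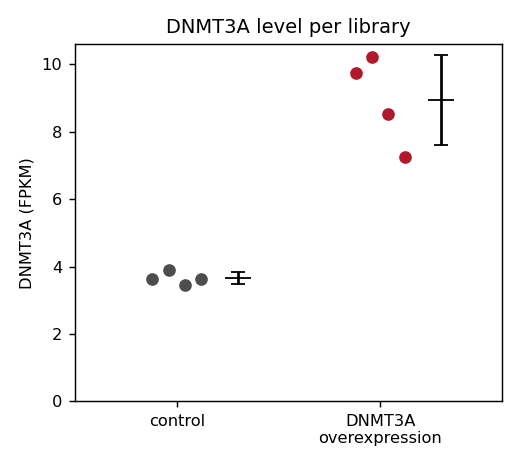
DNMT3A in FPKM (vertical axis) for each control and DNMT3A library (points), with the mean and SD of each group of 4 beside them. The control libraries lie between 3.45 and 3.89 FPKM and the DNMT3A libraries between 7.26 and 10.2 FPKM.

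AFP, the fetal serum protein, was among the genes that rose most. It rose from 370 ± 9.28 to 1143 ± 192 FPKM (log2 1.61), and the fibrinogen chains FGB (log2 1.61), FGA (log2 1.22) and FGG (log2 0.94) and the thyroxine carrier TTR (log2 1.38) rose with it. ALB, at 6188 FPKM in the controls, had a log2 fold change of 0.00. SCARA3 rose by a log2 of 1.86, N-cadherin (CDH2) by 1.64, HSPA1B by 1.52, UGT2B4 by 1.39, RSRP1 by 1.38, NT5E by 1.31 and PCK1, a gluconeogenic enzyme, by 1.30. Even in the DNMT3A libraries UGT2B4 (2.18 to 2.81 FPKM) and PCK1 (1.43 to 2.47 FPKM) were low, close to the filter's mean FPKM of 1. Falls were ranked on the log2(FPKM + 1) scale among protein-coding genes past the FPKM filter and the threshold whose groups did not overlap. Among these TNNI2, a troponin subunit of skeletal muscle, fell most, from 12.5 ± 2.88 to 0.944 ± 0.233 FPKM (log2 -2.78). Other falls were those of GSTA1 (log2 -1.54), SELENOM (log2 -1.25), osteopontin (SPP1, log2 -1.24), HIST1H2BK (log2 -1.22), ZSCAN31 (log2 -1.09), UNC13D (log2 -1.07), SEL1L3 (log2 -1.06), ABRACL (log2 -1.06) and GSTA2 (log2 -1.04). GSTA1 with GSTA2, and HSPA1A with HSPA1B, are near-identical copies whose reads the authors' counting could split, so their separate values are uncertain.

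In total 2389 of 11620 tested genes changed, 1154 up and 1235 down, and 82 changed at least 2-fold, 50 up and 32 down. The median size of a called change was 0.35 on the log2 scale. The groups did not overlap for 2192 of the 2389 genes, and for 25.1% of all tested genes against 2.86% by chance. The count was 3756 with array weights, 1551 without control library 2 and 1508 without control library 3, and the count of 2-fold changes was 171 with a pseudocount of 0.1. Without a filter 810 rose and 786 fell of 30436 genes, and 56.8% of the 2389 calls were kept. With alternatives chosen after the data were seen, that count was 170 with voom and 38 among protein-coding genes only.

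Part of these changes followed chromosome position. Of 114 tested genes starting between 20 and 45 Mb on chromosome 14, 88 rose and 0 fell, with a median log2 fold change of 0.49. The block's median deviation from the control mean was 0.45, 0.46, 0.52 and 0.53 in DNMT3A libraries 1 to 4 and between -0.01 and 0.02 in the controls. The bounds of the block were chosen after these fold changes were seen, so no p-value is given for it. From 45 Mb onward 30 of 277 genes rose and 29 fell, with a median of -0.01. The block held 38 of the 199 genes that rose at least 1.5-fold. On chromosome 13, 66 of 199 tested genes fell and 9 rose, with a median of -0.15. That chromosome's median deviation from the control mean was -0.13, -0.22, -0.14 and -0.10 in DNMT3A libraries 1 to 4 and between -0.02 and 0.02 in the controls. Without chromosomes 13 and 14, a choice made after these values were seen, 2099 of 11026 genes changed, 997 up and 1102 down.

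**Figure D2:**
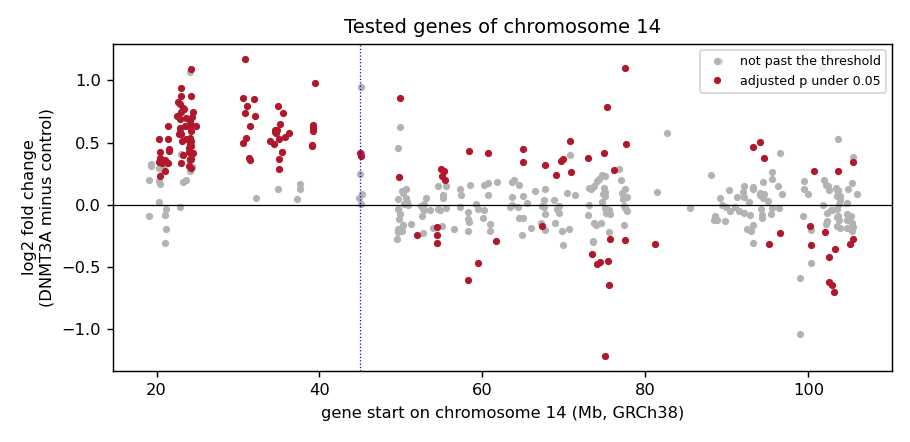
Log2 fold change (vertical axis) of each tested gene against its start on chromosome 14 in Mb (horizontal axis); red points passed the threshold and the dotted line marks 45 Mb. The 114 genes starting between 20 and 45 Mb have a median of 0.49, and the 277 genes beyond have a median of -0.01.

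Of 27 tested targets of p53, 14 rose, 0 fell and 13 did not pass the test (14 rose and 0 fell adjusted over the list alone), with a median log2 of 0.31. BTG2 rose by a log2 of 0.85, GDF15 by 0.74, EDA2R by 0.72 and the death receptor TNFRSF10B by 0.66, while CCNG1 (log2 -0.02) and FDXR (log2 -0.06) did not pass the test. CDKN1A (log2 0.59) and MDM2 (log2 0.31) also rose; both were chosen after their values were seen. At the preset correlation camera gave an adjusted p of 2.43e-06, and the adjusted p = 0.108 with an estimated correlation.

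Of 26 tested genes of glutathione metabolism and the NRF2 response 15 fell, 0 rose and 11 did not pass the test (19 fell and 0 rose adjusted over the list alone), with a median log2 of -0.31. The cystine transporter SLC7A11 fell by 1.04 on the log2 scale, AKR1B10 by 0.66, AKR1C1 by 0.47 and OSGIN1 by 0.47, and the ferritin chain FTH1 (log2 -0.62) and GPX2 (log2 -0.10) did not pass the test. Camera's adjusted p at the preset correlation was 2.43e-06, and the adjusted p = 0.266 with an estimated correlation. Of 15 genes of serine, glycine and one-carbon synthesis 9 fell and 0 rose (9 and 0 adjusted over the list alone), among them ALDH1L1 (log2 -0.54), PSAT1 (log2 -0.53), MTHFD2 (log2 -0.41) and MTHFD1L (log2 -0.41); SHMT2 (log2 -0.18) did not pass. The camera adjusted p was 0.000293, and the adjusted p = 0.27 with an estimated correlation. Of 21 genes of amino acid and urea metabolism 8 fell and 0 rose (8 and 0 adjusted over the list alone), among them GNMT (log2 -0.81), the urea cycle enzyme ASS1 (log2 -0.79), CTH (log2 -0.74) and GPT (log2 -0.43); GLUD1 had a log2 of -0.07. At the preset correlation camera gave an adjusted p of 0.00578, and the adjusted p = 0.27 with an estimated correlation. Calls were lost for OSGIN1 without control library 1, 2 or 4 or DNMT3A library 1, 3 or 4 (limma adjusted p = 0.0552 to 0.0886), for GPT without control library 1, 2 or 3 or DNMT3A library 1, 3 or 4 (0.0517 to 0.0985) and with the length and GC correction (0.0639), and without a filter for OSGIN1 (0.122), GPT (0.119) and MTHFD2 (0.0609). FTH1 passed the threshold without DNMT3A library 2 (0.0367) or 4 (0.0226), with array weights (0.0129), with the replicate number as a block (0.0332), with voom (0.0193) and among protein-coding genes only (0.0257).

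The heat shock, endoplasmic reticulum stress and immediate early lists were each called up by camera at the preset correlation. Of 20 heat shock genes 9 rose and 3 fell (9 and 3 adjusted over the list alone): HSPA1A (log2 1.26) and DNAJB4 (log2 0.90) rose and the small heat shock protein HSPB1 fell (log2 -0.60), while HSP90AB1 (log2 0.04) and HSPD1 (log2 -0.01) did not pass. Camera's adjusted p at the preset correlation was 0.00123, and the adjusted p = 0.27 with an estimated correlation. Of 23 genes of endoplasmic reticulum stress 5 rose and 0 fell (5 and 0 adjusted over the list alone), among them DNAJB9 (log2 1.07), HERPUD1 (log2 0.71), SYVN1 (log2 0.44) and MANF (log2 0.25); the abundant chaperones CALR (log2 0.06) and HSP90B1 (log2 0.19) did not pass. The camera adjusted p was 0.00237, and the adjusted p = 0.206 with an estimated correlation. Of 23 immediate early and MAPK feedback genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), among them DUSP6 (log2 1.01), FOS (log2 0.79), SPRY4 (log2 0.78) and EGR1 (log2 0.75); MYC (log2 -0.14) did not pass. At the preset correlation camera gave an adjusted p of 0.00237, and the adjusted p = 0.27 with an estimated correlation. Calls were lost for HSPB1 without control library 1, 2 or 3 or DNMT3A library 1 or 3 (limma adjusted p = 0.0758 to 0.112) and with quantile normalization (0.0584), for MANF without control library 1, 2, 3 or 4 or DNMT3A library 2 or 3 (0.0514 to 0.0886), and without a filter for HSPB1 (0.147) and MANF (0.075). HSP90B1 passed the threshold without DNMT3A library 2 (0.0125) and with array weights (0.00728), the length and GC correction (0.0143), quantile normalization (0.0214) and voom (0.0202).

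Of 23 hypoxia genes 10 rose and 1 fell (12 and 2 adjusted over the list alone): BHLHE40 (log2 1.02), KDM3A (log2 0.79), HILPDA (log2 0.67) and INSIG2 (log2 0.63) rose, CA9, named after its value was seen, fell (log2 -0.55), and the glucose transporter SLC2A1 (log2 -0.25) did not pass. Camera's adjusted p at the preset correlation was 0.00356, and the adjusted p = 0.711 with an estimated correlation. Of 29 apoptosis regulators 8 rose and 1 fell (10 and 2 adjusted over the list alone), among them BCL2L2 (log2 0.78), which lies in the chromosome 14 block, APAF1 (log2 0.56) and the survival factor MCL1 (log2 0.50); CASP8 fell (log2 -0.30). Its camera adjusted p was 0.0308, and the adjusted p = 0.266 with an estimated correlation. The apoptosis list shares BAX, BBC3, FAS and TNFRSF10B with the p53 list, so these calls are not independent. Of 16 TGF-beta and SMAD targets 8 fell and 2 rose (10 and 2 adjusted over the list alone): INHBE (log2 -0.78), SKIL (log2 -0.70) and ID2 (log2 -0.54) fell, JUNB (log2 0.60) rose and ID1 (log2 -0.15) did not pass. The camera adjusted p was 0.00578, and the adjusted p = 0.206 with an estimated correlation. Calls were lost for CA9 without control library 2 (limma adjusted p = 0.0544) and without a filter (0.0793), and for BHLHE40 without a filter (0.074). SLC2A1 passed the threshold without DNMT3A library 2 (0.0217), with array weights (0.0137), with the length and GC correction (0.0101), with voom (0.0453) and among protein-coding genes only (0.0359).

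Most tested genes of oxidative phosphorylation (49 of 56), the ribosome (63 of 75) and fatty acid oxidation (20 of 25) did not pass the test, and more of those that passed were lower than higher. Of 56 nuclear genes of oxidative phosphorylation 7 fell and 0 rose (5 and 0 adjusted over the list alone; median log2 -0.11), among them UQCRQ (log2 -0.43), ATP5F1D (log2 -0.43), NDUFC1 (log2 -0.33) and SDHD (log2 -0.30); ATP5F1B (log2 -0.10) did not pass. At the preset correlation camera gave an adjusted p of 0.00315, and the adjusted p = 0.711 with an estimated correlation. Of 75 ribosomal protein genes 9 fell and 3 rose (3 and 2 adjusted over the list alone; median log2 -0.10): RPS28 (log2 -0.61) and RPS10 (log2 -0.47) fell, RPS23 (log2 1.09) and RPL30 (log2 0.54) rose and RPS12 (log2 -0.17) did not pass. Camera's adjusted p at the preset correlation was 0.0227, and the adjusted p = 0.767 with an estimated correlation. Of 25 genes of fatty acid oxidation 4 fell and 1 rose (5 and 1 adjusted over the list alone): SLC27A2 (log2 -0.34), CPT2 (log2 -0.29) and ECH1 (log2 -0.23) fell and ACAA1 (log2 0.24) rose. The camera adjusted p was 0.0227, and the adjusted p = 0.711 with an estimated correlation. Leaving out 1 library ended the call of SDHD (control library 2 or 3 or DNMT3A library 1; limma adjusted p = 0.0566 to 0.0745), RPS28 (control library 1, 2, 3 or 4 or DNMT3A library 3; 0.064 to 0.111), SLC27A2 (control library 1 or 2 or DNMT3A library 1 or 3; 0.0538 to 0.0585), CPT2 (control library 1, 3 or 4 or DNMT3A library 1, 2 or 3; 0.0501 to 0.0734) and ECH1 (control library 1, 2 or 4 or DNMT3A library 1; 0.0596 to 0.0725). Without a filter these calls and that of RPS23 were also lost (0.0524 to 0.158). Calls also ended with quantile normalization for RPS28 (0.0614) and ECH1 (0.0563), without a trend for RPS28 (0.0535) and with array weights for ECH1 (0.062). The replicate number as a block ended those of CPT2 (limma adjusted p = 0.0699), ECH1 (0.0757) and SDHD (0.0592).

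**Figure D3:**
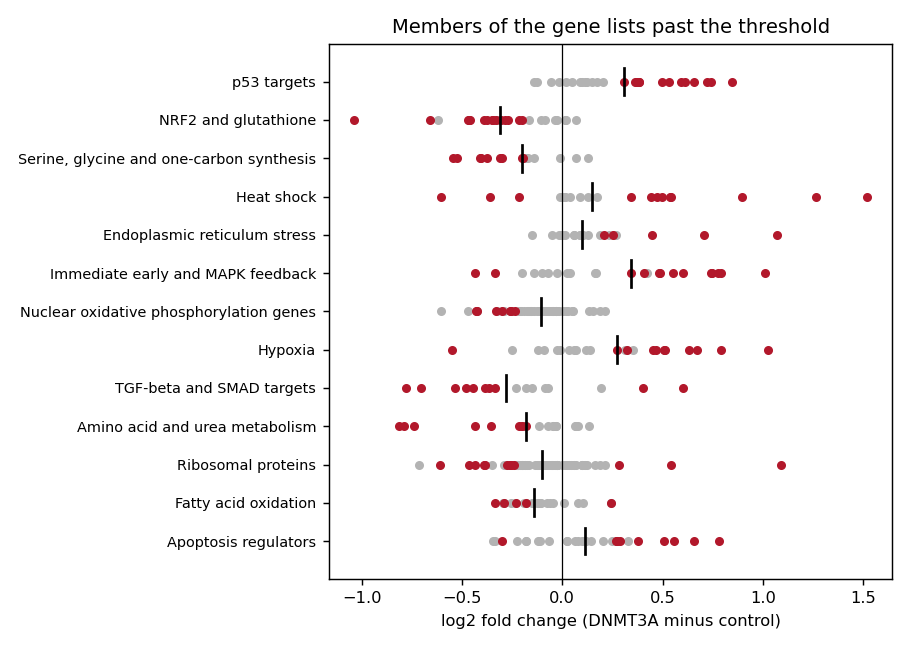
Log2 fold change (horizontal axis) of each tested member of the 13 gene lists past the threshold at the preset correlation; red points are members with an adjusted p under 0.05, grey points the others, and the black bar is the list's median. The p53 list has a median of 0.31 and the NRF2 list a median of -0.31.

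Across the 43 lists tested, camera at the preset correlation called 13, 6 up and 7 down; at an estimated correlation it called 0, with 7 at an unadjusted p under 0.05, and fry called 19 in 1 direction. Among the 35 splits of the same libraries 3 gave as many lists, the real one included. The others of these kept most controls together and so part of the real contrast. The ribosomal list lost its call without control library 1 (camera adjusted p = 0.351), DNMT3A library 2 (0.0546) or DNMT3A library 4 (0.0999), the fatty acid oxidation list without control library 1 (0.0791) or DNMT3A library 2 (0.0546), and the apoptosis list without control library 4 (0.0637) or DNMT3A library 4 (0.0608). The fatty acid oxidation (0.0508) and apoptosis (0.0801) lists also lost it without chromosomes 13 and 14. Quantile normalization ended the calls of the ribosomal list (camera adjusted p = 0.237) and the fatty acid oxidation list (0.0651), and array weights ended those of the ribosomal (0.424), fatty acid oxidation (0.115) and apoptosis (0.0779) lists.

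Lists of liver identity held genes that rose and genes that fell and were not called by camera at the preset correlation. Of 24 liver transcription factors 4 rose and 2 fell (6 and 3 adjusted over the list alone): CEBPA fell from 45.3 ± 4.76 to 23.1 ± 4.98 FPKM (log2 -0.96), NR0B2 (log2 0.65) and FOXA3 (log2 0.38) rose and HNF4A (log2 0.18) did not pass. Of 24 secreted liver proteins 5 rose and 2 fell (5 and 4 adjusted over the list alone), and APOH (log2 -0.25) did not pass. The list's camera adjusted p was 0.12, and it passed the threshold without a filter (0.0282), with quantile normalization (0.039), with array weights (0.00977), without control library 1 (0.0397) and without DNMT3A library 2 (0.0481). Of 15 fetal and progenitor markers 4 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.503), with AFP higher, EPCAM lower (log2 -0.39) and GPC3 (log2 -0.04) not past the test. Of 20 genes of the ATF4 response 9 fell and 3 rose (10 and 4 adjusted over the list alone), with NUPR1 lower (log2 -0.58) and ATF4 itself at a log2 of 0.00. Its camera adjusted p was 0.11, and the list passed the threshold without a filter (0.0124) and with members matched by gene ID (0.0429). Of the genes named here, FOXA3 lost its call without control library 3 (limma adjusted p = 0.0543) and without a filter (0.0632), and NUPR1 without control library 2 (0.0541) and without a filter (0.0751). HNF4A passed the threshold without DNMT3A library 4 (0.0149), and APOH with the length and GC correction (0.0438) and with voom (0.0426).

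Imprinted genes and tumour suppressors known to be silenced by methylation showed no common direction among the members that passed the FPKM filter. Of 35 listed imprinted genes 16 were tested, and of 35 listed suppressors 14, so members with a mean FPKM under 1 were not covered. The list of 45 cancer-testis and germline genes had 0 tested members. Of 16 tested imprinted genes 2 rose and 3 fell (3 and 3 adjusted over the list alone), with GRB10 lower (log2 -0.40) and DLK1 (log2 0.27) and PEG3 (log2 0.27) higher. Of 14 methylation-silenced tumour suppressors 2 rose and 2 fell (2 and 2 adjusted over the list alone): DAPK1 (log2 0.44) and E-cadherin (CDH1, log2 0.28) rose and PYCARD (log2 -0.50) and CASP8 fell. For the imprinted list the median was 0.02, the mean -0.02 and the test's direction down. Calls were lost for DLK1 without control library 2 or 3 or DNMT3A library 1 or 3 (limma adjusted p = 0.0503 to 0.069), for CDH1 without DNMT3A library 3 (0.0542), for PYCARD without control library 1, 2 or 3 or DNMT3A library 2 (0.0594 to 0.0898), and without a filter for DLK1 (0.0607) and PYCARD (0.125).

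The number of genes at an FPKM of at least 1 was 11646 ± 97.9 in the controls and 11761 ± 120 in the DNMT3A libraries (exact permutation p = 0.2). The 13 mitochondrially encoded protein genes made up 29.5% ± 2.88 of summed FPKM in the controls and 28.3% ± 2.05 in the DNMT3A libraries (exact permutation p = 0.571). Within them MT-ND1 fell (log2 -0.58) and MT-ND3 fell (log2 -0.34), and MT-CO1 (log2 -0.15) did not pass the test. Without a filter MT-ND1 (limma adjusted p = 0.277) and MT-ND3 (0.614) lost their calls, and MT-ND3 also with quantile normalization (0.314). As a list they were not called (camera adjusted p = 0.216), except without control library 1 (0.0305).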

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

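The tests of the p53 list on its own were chosen after the result was seen. In a group of 4, chance sets 1 library apart from the others in about 5% of groups, which makes 13.3 of the 266 groups examined, and 18 were found.

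Single libraries stood apart from the other libraries of their group for these genes. In DNMT3A library 1 UGT2B4 was 2.81 FPKM. In DNMT3A library 2 PCK1 was 1.43, HSP90B1 309, GLUD1 190, GPC3 943, DAPK1 6.33 and CDKN1A 46.9 FPKM. In DNMT3A library 3 SELENOM was 1.95, SYVN1 21.5 and NR0B2 59.8 FPKM. In DNMT3A library 4 HSP90AB1 was 1154, MYC 43 and HILPDA 2.88 FPKM, and the mitochondrial share was 31.4%. Among the controls ACAA1 was 14.5 and RPL30 24.5 FPKM in library 1, ABRACL 10.5 in library 2 and E2F1 29.5 in library 4. Below the filter on low values, in genes that the comparisons left out, 142 rose and 94 fell of 18816 when no filter was set. Of those that fell KCNH5, chosen after its values were seen, had 1149 recovered reads over the controls and 0 over the DNMT3A libraries, and MED12L, chosen likewise, had 274 and 11. Of those that rose SPINK1 had 3 and 102 reads and PRAME 50 and 311, both also chosen after their values were seen. Other calls below the filter rested on few reads. Examples, chosen likewise, were GSTM2P1 (0 reads over the controls and 4 over the DNMT3A libraries), MIR551A (0 and 7) and AC040160.2 (4 and 0).

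The real split of the 8 libraries gave 2389 changed genes and 82 changed at least 2-fold. Of the 35 splits into 4 and 4 only that 1 gave as many, the highest of the others being 1 gene in each case. A share of 1 in 35 is the smallest these splits can give, so chance is unlikely for both counts but not excluded. The splits do not show what set the groups apart. For the number of lists chance stays open: 3 of 35 splits gave at least the 13 lists of the real one, and the highest other gave 15. That split set control libraries 1, 2 and 4 with DNMT3A library 3, and the remaining one set control libraries 1, 3 and 4 with it. Such splits keep part of the real contrast, so they are not free of a group difference. Splits with equal numbers of control and DNMT3A libraries on each side gave at most 8 lists. Along the chromosomes, the median of 100 consecutive genes lay up to 0.542 from that of all tested genes, in the block at the start of chromosome 14, where a bound of 0.2 had been set before the result was seen. The values of the block are consistent with a copy-number difference between the infected cell pools, which may have arisen in selection of the cells and need not involve DNMT3A's activity. DNA was not analysed here, and a regional effect of DNMT3A on this block stays open and untested. On chromosome 13, where the median fold change was -0.15, the farthest of 100 such windows lay at -0.183, short of the bound of 0.2, so the test did not point to a copy-number difference there and the explanation of that shift stays open.

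For the calls of the p53 list as up and the NRF2 list as down, the tables argue against gene length and GC content: the lists kept at least 81.4% of their medians after the correction. Subtracting the nearest 20 genes left 117.7% of the p53 median, and leaving out DNMT3A library 4 left 91.6%, with the other DNMT3A libraries outside the control range. These values argue against copy number of their neighbourhoods and against that library as the source of the p53 call. Both readings of the p53 list alone were chosen after the result was seen. The tests set in advance took together the p53 and NRF2 lists, whose camera p at the preset correlation was the smallest, and were undecided. They were set before their own results, for calls already seen. The NRF2 list kept 78.8% and 76.7% in these tests, short of the bound of 80% set in advance although its call stood without library 4 (camera adjusted p = 6.04e-06) and the other DNMT3A libraries lay outside the control range, so a contribution of copy number or of library 4 cannot be told apart from DNMT3A there. No test here separated an effect of DNMT3A from another difference between the infected cell pools, and both stay open for both lists.

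For the calls of the ribosomal protein and nuclear oxidative phosphorylation lists as down, the length and GC correction kept at least 94% of the medians. Without DNMT3A library 4 the ribosomal list kept 78.8%, was no longer past the threshold (camera adjusted p = 0.0999 against 0.0227) and had 0 of the other DNMT3A libraries outside the control range, so a contribution of that library cannot be told apart from the group there. The oxidative phosphorylation list kept 81.3%, just over the bound of 80% set in advance, stayed past the threshold (camera adjusted p = 0.00498) and had 2 of the other DNMT3A libraries outside the control range. The ribosomal list depended more on control library 1 than on DNMT3A library 4. Its median was -0.063 without the former (camera adjusted p = 0.351) and -0.079 without the latter. Its call was also lost without DNMT3A library 2 (0.0546). No biological explanation was tested for the ribosomal or the oxidative phosphorylation list.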

How the results depend on the processing

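Voom, protein-coding genes only, the length and GC correction, matching by gene ID and leaving out chromosomes 13 and 14 were chosen after the data were seen. DNMT3A stayed higher and past the threshold under every alternative run, with a log2 fold change of 1.01 to 1.30. The number of genes changed was 3756 with array weights and 1508 to 2443 when 1 library was left out, lowest without control library 3 and at 1551 without control library 2, where fewer samples were tested. Without a filter 810 genes rose and 786 fell, and 56.8% of the calls of the main fit were kept. Genes changed at least 2-fold numbered 171 with a pseudocount of 0.1 and 170 with voom, which do not compress low values as a pseudocount of 1 does, and 38 among protein-coding genes only, which leaves out genes of other classes. Camera with an estimated correlation, which allows for members that vary together, called 0 lists. Its p also rose where the estimate lay below the preset 0.01. The unadjusted camera p went from 0.00932 to 0.0259 for the apoptosis list (estimate -0.0085). For the TGF-beta list (estimate -0.026) it went from 0.00129 to 0.0136. The lost calls alone therefore do not show that members varied together. With the replicate number as a block 1881 genes and 13 lists were called; the number marks no stated pairing, and 2 of 8 libraries correlated best with their own number. Of the 105 named genes past the threshold besides DNMT3A, 105 kept their sign in every alternative run, 81 were past the threshold in each, and 86 were past it when any 1 library was left out. Of the 25 named genes not past the threshold 12 changed sign, all by small values whose cause was not tested. Median-ratio scaling gave HSPD1 0.00. Quantile normalization gave UHRF1 0.016, CCNG1 0.064, GLUD1 0.033, MT-CO1 0 and the mitochondrially encoded list a median of 0. Array weights gave DNMT1 -0.016, CCNG1 0.038, HSPD1 0.023, GPC3 0.007 and ACTA2 0.051. Voom gave UHRF1 0.007, CCNG1 0.006 and HSPD1 0.012. The length and GC correction gave DNMT1 -0.029, CCNG1 0.011 and FDXR 0.013. Leaving out 1 library gave ALB -0.051 to 0.115, ATF4 -0.038 to 0.042, ACTA2 -0.148 to 0.081, GLUD1 -0.105 to 0.003, GPC3 -0.071 to 0.025, HSPD1 -0.036 to 0.017, UHRF1 -0.101 to 0.024, CCNG1 -0.072 to 0.078, DNMT1 -0.044 to 0.093 and CALR -0.002 to 0.121. Without a filter the imprinted list's test turned up, with a median of 0.021. Of the 22 lists not described singly, none past the threshold, the test's direction changed in 6 and 3 passed the threshold in an alternative; medians near 0 changed sign in further lists. What depth limits was not tested; the FPKM filter also left out long genes with many reads.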

Other observations

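The 33 groups of at least 10 tested genes that the table itself names, transcription factor families and gene classes, were tested after the data were seen, and 4 passed the threshold of camera at the preset correlation. Of 20 tested mitochondrial transfer RNA genes 10 fell and 2 rose, with a median log2 of -0.92 (camera adjusted p = 0.00713, and adjusted p = 0.282 with an estimated correlation). RNA was captured on poly-T beads and the preferred fragment length was 370 to 420 bp. These values therefore need not reflect mature transfer RNA, and reads of adjoining transcripts were not told apart. Of 341 zf-C2H2 zinc finger genes 51 rose and 24 fell, with a median log2 of 0.06 (camera adjusted p = 0.0464, and adjusted p = 0.442 with an estimated correlation). Of 14 genes of the ARID family 4 rose and 0 fell, with a median log2 of 0.16 (camera adjusted p = 0.00713, and adjusted p = 0.442 with an estimated correlation). Of 77 sense intronic genes 7 rose and 1 fell, with a median log2 of 0.12 (camera adjusted p = 0.0464, and adjusted p = 0.643 with an estimated correlation); these overlap other genes, so without strand their reads cannot be told apart.

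Some genes stood out in lists that were not called. The glycolytic regulators HK2 (log2 0.98) and PFKFB3 (log2 0.88) rose, E2F1 (log2 0.38) and CENPE (log2 0.54) rose and RRM2 (log2 -0.26) fell. The Wnt targets SP5 (log2 -0.80) and NOTUM (log2 -0.42), the acyltransferase AGPAT2 (log2 -0.91), the iron-siderophore binder LCN2 (log2 -0.84), HLA-B (log2 -0.55) and the viral RNA sensor IFIH1 (log2 -0.23) fell. Markers of other cell types had few tested members: LCP1 (log2 -0.80), on chromosome 13, and ENG (log2 -0.54) fell, LYZ (log2 0.48) rose and ACTA2 had a log2 of -0.06. Calls were lost for RRM2 without control library 2 or 3 or DNMT3A library 1 (limma adjusted p = 0.0568 to 0.0684) and with quantile normalization (0.0751), for NOTUM without control library 1, 2 or 3 or DNMT3A library 1 or 3 (0.055 to 0.07) and without a filter (0.0949), and for IFIH1 without control library 2 or 3 or DNMT3A library 3 (0.0519 to 0.065). The replicate number as a block also ended the call of IFIH1 (limma adjusted p = 0.0639).

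One hypothesis was that genes with CpG-rich 5′ ends would fall in the DNMT3A libraries. CpG content was taken from the first 500 bases of each gene's longest transcript, not from the promoter. The mean log2 level of the quartile richest in CpG minus that of the poorest changed by -0.034 (two-sided exact permutation p = 0.0571), in the direction of the hypothesis and short of the threshold, so it stays undecided. This contrast was 0.704 to 0.742 in the control libraries and 0.665 to 0.721 in the DNMT3A libraries, with DNMT3A library 1 inside the control range. Of 2759 genes in the richest quartile 355 fell and 278 rose, and of 2759 in the poorest 276 fell and 293 rose.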
